A study of Mus musculus with 12 samples.

How the data were processed

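The study profiled alveolar macrophages from bronchoalveolar lavage of bleomycin-treated mice in 12 libraries, 4 in each of the groups titled UPBIG, UPSMALL and DOWN. Full-length cDNA was made from polyadenylated RNA without prior RNA extraction, so unequal transcript capture and amplification are part of every value. The deposited values are RSEM expected counts per gene and library, made by the authors from reads aligned with STAR to mm10, as the submitters' processing notes name these tools. Versions, the annotation release and the strand setting are not given in the sources used here, so antisense partners cannot be told apart. The table holds 26855 genes, genes with a total of 0 are absent, and 13.8% of values are not whole. Gene symbols and coordinates came from a mouse annotation of the same assembly, and 26775 identifiers matched a symbol.

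Counts were rounded to whole numbers and filtered with edgeR's filterByExpr on the groups, which left 12625 genes. All 12 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood F tests, no block). Each pair of groups was compared, and a joint test asked for any difference among the 3 groups. Benjamini-Hochberg adjusted p under 0.05 counted as a call, and a standard error is the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library totals and are given as mean ± SD of 4 libraries. Ratios and floors use summed counts, with a floor of 3 counts over the group and 95% intervals. PCR reads without molecular identifiers are not independent molecules, so these cover counting error only. Library totals of 17109669 to 23282621 set the precision of each value.

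The design, the tests, the 34 gene lists (25 of programmes and 9 of other cell types, with 910 members, 888 of them with a count) and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members, 31 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 93 list tests. They were tested again with the correlation estimated from the data, and with fry. Camera sets the list against all other genes; fry does not. Counts adjusted over the list alone stand beside those over all genes. Lists share members, so their results are not independent.

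The rule named, in each comparison, the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 3 and no overlap between the libraries of the groups, leaving out ribosomal protein, mitochondrial and unnamed genes. It added up to 3 called members with the smallest p in the direction of each called list, and always Siglecf, Pparg, Fabp4, Plin2, Cidec, Spp1, Gpnmb, Trem2, Cd9, Itgam and Mki67. It gave 102 distinct genes, and the text names a part of them. Members named to identify a count of 5 or fewer, such as Car4, Thbs1 and Bst2, and Ccdc127 beside Lrrc14b, were chosen after their values were seen. Some genes that the rule names are not reported here.

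Per-library measures were compared with two-sided exact permutation tests, adjusted over 21 tests. Shared calls were set against independent lists, against 20 simulated data sets without effect that share a group, and against a division of the shared group. The alternatives were DESeq2-style size factors, library totals alone, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a stricter filter of 5 CPM in 4 libraries, the replicate number as a block, only the 8 libraries compared, a minimum fold of 1.5 and each library left out in turn. The methods were also tested on simulated data with known changes, drawn from the spread that edgeR fitted to these libraries. There edgeR recovered 52.5% to 60.6% of 2-fold and 75.8% to 78.9% of 4-fold changes and called 5 or 6 unchanged genes per comparison. Reads were not used here.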

Results

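Bronchoalveolar lavage was collected from mice on day 14 after bleomycin, a drug that injures the lung and is widely used to model pulmonary fibrosis. Alveolar macrophages were filtered by size into fractions rich or poor in border-associated alveolar macrophages and sorted by side scatter and by BODIPY, a dye that stains neutral lipid. The 12 libraries, made with full-length SMART-Seq chemistry from lysed cells, fall into 3 groups of 4, titled UPBIG, UPSMALL and DOWN. The labels do not say which title stands for which filter fraction or sorting gate, so the titles serve as group names throughout. Library totals ranged from 17109669 to 23282621 expected read counts, and 12625 genes were tested. The labels do not say that the replicates came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

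UPSMALL lay between UPBIG and DOWN on the main axis of variation. Principal component 1, which held 28.6% of the variance, ran from -60.5 to -40.9 in the UPBIG libraries, from -3.99 to 10.6 in UPSMALL and from 40.6 to 48.5 in DOWN. By a test of any difference among the groups, 1736 genes changed. Of 31 gene lists tested, camera with a preset correlation called 18 between UPBIG and UPSMALL, 18 between UPBIG and DOWN and 14 between UPSMALL and DOWN; 8, 10 and 6 of these held with an estimated correlation, and fry, which asks whether a list's own genes move one way, called 16, 19 and 14. On average the UPBIG libraries were also less diverse. They held 15674.5 ± 582 detected genes (SD, n = 4) against 16578.8 ± 366 in DOWN and 16728.8 ± 723 in UPSMALL. The macrophage lysozyme Lyz2 and the ferritin chains Ftl1 and Fth1 took 27.6% ± 1.14 (SD, n = 4) of UPBIG counts, 21.3% ± 3.88 of UPSMALL counts and 20.6% ± 1.11 of DOWN counts. UPSMALL replicate 4 held 15.5%, against 22.3% to 23.8% in the other UPSMALL libraries, and had the lowest limma-voom quality weight (0.453). Mitochondrially encoded transcripts took 4.62% ± 0.473, 3.03% ± 0.359 and 2.87% ± 0.277, and the ribosomal RNA-like transcript CT010467.1 took 0.763% ± 0.336, 0.566% ± 0.360 and 0.0981% ± 0.00832. The UPBIG and DOWN libraries did not overlap in any of these measures (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.06 after adjustment over 21 such tests). For UPBIG against UPSMALL, the exact permutation p was 0.0857 for genes detected, 0.457 for CT010467.1 and 0.0286 for the shares of the abundant and the mitochondrial transcripts. After adjustment over the 21 tests these became 0.15, 0.6 and 0.06, so none passed.

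**Figure D1:**
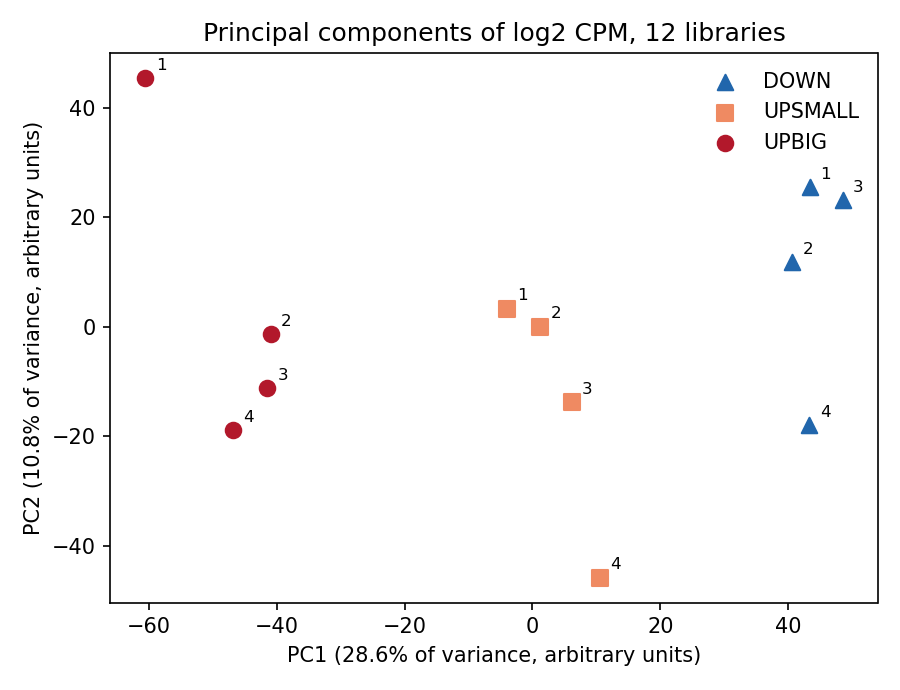
Each point is a library, placed by its scores on principal components 1 and 2 of log2 CPM (arbitrary units, with the percent of variance on each axis), coloured by group and numbered by replicate. Component 1 holds 28.6% and component 2 holds 10.8% of the variance, and the UPSMALL libraries, at -3.99 to 10.6 on component 1, lie between UPBIG and DOWN.

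UPBIG cells had higher transcripts of liver X receptor targets and fatty acid oxidation than DOWN cells, and lower transcripts of cholesterol synthesis, antigen presentation and monocyte origin. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, stood at 132 ± 12.2 CPM in UPBIG (SD, n = 4), 9.65 ± 1.68 in UPSMALL and 2.88 ± 0.596 in DOWN, a log2 fold change of 5.52 ± 0.18 (SE) between UPBIG and DOWN with adjusted p = 2.15e-13. Apoc1, which encodes an apolipoprotein, stood at 306 ± 78.9, 42.7 ± 6.28 and 12.2 ± 2.64 CPM (SD, n = 4), a log2 fold change of 4.65 ± 0.21. In the other direction, Stard4, which encodes a sterol carrier, fell by 2.58 ± 0.22 on the log2 scale. Cx3cr1, the fractalkine receptor found on monocytes and cells derived from them, fell by 4.75 ± 0.32. In all, 2210 genes differed, 1140 higher and 1070 lower in UPBIG, and 912 of them by more than 2-fold.

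In this comparison cholesterol synthesis genes fell, while liver X receptor targets and fatty acid oxidation genes rose. Of 25 tested cholesterol synthesis genes, 22 fell (23 lower adjusted over the list alone, median log2 fold change -1.81; camera adjusted p = 0.00522 with an estimated correlation). Besides Stard4 they included Fdft1, squalene synthase, at -2.29 ± 0.14. The strand setting of the counting is not given, and Fdft1 overlaps Ctsb on the other strand. Of 19 targets of the liver X receptors, which respond to sterols, 12 rose (12 adjusted over the list alone, median 0.62; adjusted p = 0.00128 with an estimated correlation). Among them the cholesterol exporters Abca1 and Abcg1 rose by 2.59 ± 0.17 and 1.89 ± 0.14 on the log2 scale. Fatty acid oxidation genes rose in 15 of 29 cases (16 adjusted over the list alone, median 0.40; adjusted p = 0.0116 with an estimated correlation). That median became 0.08 with library totals alone. The thioesterase Acot1 stood at 3.80 ± 0.34 and the dehydrogenase Acadl at 1.27 ± 0.11. Pdk4, a kinase that restrains glucose oxidation, had 946 counts over the UPBIG libraries and 8 over the DOWN libraries, a depth-scaled ratio of 155 (95% counting interval 78.6 to 361). Its fitted log2 fold change was 7.22, and 8.59 without DOWN replicate 1. Lipid droplet genes rose in 12 and fell in 3 of 27 cases (12 and 3 adjusted over the list alone, median 0.45; adjusted p = 0.0221 with an estimated correlation). Mgll, a lipase that releases fatty acid from monoglycerides, stood at 3.31 ± 0.16, and the droplet coat genes Plin2 and Plin3 at 1.56 ± 0.15 and 1.16 ± 0.11. The droplet genes that fell were Acsl3, Agpat2 and Soat2, enzymes of lipid synthesis, at -1.24, -0.83 and -4.18. Cidec, a droplet fusion gene, was higher by 1.28 ± 0.36 (adjusted p = 0.0199), a call that ended without UPBIG replicate 1 or DOWN replicate 1 (adjusted p = 0.0574 to 0.0735). Lipid and lipoprotein uptake genes rose in 10 and fell in 3 of 20 cases (10 and 4 adjusted over the list alone, median 0.44; adjusted p = 0.0101 with an estimated correlation). The fatty acid transporter Cd36 rose by 2.58 ± 0.23, the fatty acid carrier Fabp4 by 2.57 ± 0.21 and the lipoprotein lipase Lpl by 0.98 ± 0.11. Among the genes that fell were the scavenger receptors Msr1 and Scarb1, at -0.76 each. Fatty acid synthesis genes did not move together (1 higher, Scd1, and 4 lower, Acly, Acss2, Fads1 and Fasn, of 17, with 2 and 7 adjusted over the list alone, median -0.07; camera adjusted p = 0.549).

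Genes of macrophage identity moved along the same axis. Resident alveolar macrophage genes rose in 16 and fell in 3 of 25 cases (17 and 3 adjusted over the list alone, median 0.91; adjusted p = 0.00522 with an estimated correlation). Fabp4, the eosinophil-associated ribonuclease gene Ear1, at 2.10 ± 0.16, and the lectin Siglecf, at 1.24 ± 0.16, were among those that rose. Car4, Cd200r4 and Csf2rb fell, at -2.29, -0.38 and -0.33. Of 25 genes of monocyte-derived macrophages, 10 fell and 1, Thbs1, rose (13 and 1 adjusted over the list alone, median -0.77; adjusted p = 0.00522 with an estimated correlation). The chemokine receptor Ccr2 stood at -4.22 ± 0.32 and the matrix protein gene Tgfbi at -1.60 ± 0.13. MHC class II presentation genes fell in 10 of 14 cases (12 adjusted over the list alone, median -2.33; adjusted p = 0.0116 with an estimated correlation). H2-Eb1 stood at -3.45 ± 0.24, H2-DMb1 at -1.59 ± 0.15 and H2-DMa at -1.36 ± 0.14. Markers of other leukocytes moved with them. Whether the monocyte and MHC class II genes fell within macrophages or with fewer such leukocytes cannot be told from these libraries. Dendritic cell markers fell in 9 of 15 cases and 1, Bst2, rose (11 and 1 adjusted over the list alone, median -2.83; adjusted p = 0.0141 with an estimated correlation, and 0.349 by camera under a stricter low-count filter). Flt3 had 1 count over the UPBIG libraries and 341 over the DOWN libraries, a depth-scaled ratio of 259 (95% counting interval 46.2 to 10276). Its fitted log2 fold change was -7.56, and -9.36 without UPBIG replicate 3, which held that count. T and NK cell markers fell in 12 of 18 cases (14 lower and 2 higher adjusted over the list alone, median -3.71; adjusted p = 0.0645 with an estimated correlation), with the T cell receptor chain Trbc2 at 12.6 ± 4.07 CPM (SD, n = 4) in DOWN and 0.779 ± 0.487 in UPBIG. The chemokine receptor Ccr7 stood at -4.98 ± 0.87 (-5.60 without UPBIG replicate 2). The chemokine Ccl17 stood at -3.67 ± 0.34 and the receptor Gpr171 at -3.83 ± 0.55 (-4.49 without UPBIG replicate 3).

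Of 8 further programmes called, 7 passed camera only with the preset correlation. Lysosome genes rose in 36 and fell in 4 of 60 cases (37 and 5 adjusted over the list alone, median 0.49; adjusted p = 0.101 with an estimated correlation). The protease Ctsk stood at 1.30 ± 0.11 and the proton pump subunit Atp6v1b2 at 1.06 ± 0.10, against Arsb, Ctsc, Ids and Mitf, which fell. Antioxidant genes under NRF2 rose in 14 and fell in 1, Prdx6, of 34 cases (16 and 1 adjusted over the list alone, median 0.45; adjusted p = 0.0574 with an estimated correlation). Gstm1 stood at 1.98 ± 0.23, Txn1 at 1.43 ± 0.11 and the ferritin chain Fth1 at 1.16 ± 0.15. All 11 mitochondrially encoded transcripts called, of 13, rose (11 adjusted over the list alone, median 0.97; adjusted p = 0.0567 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 23 of 74 cases and 1, Uqcrfs1, fell (36 and 1 adjusted over the list alone, adjusted p = 0.307 with an estimated correlation), with a median of 0.26 that became -0.06 with library totals alone, where the list was not called (adjusted p = 0.0524). Genes of scar-associated macrophages rose in 11 and fell in 4 of 28 cases (11 and 4 adjusted over the list alone, adjusted p = 0.368 with an estimated correlation), with a median of 0.26 that also became -0.06. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 1.83 ± 0.32 and the growth factor Igf1 by 1.52 ± 0.14. The fibronectin gene Fn1, Arg1, Pdgfb and Mmp14 fell, at -2.68, -1.77, -1.74 and -0.86. Cd9, a tetraspanin of the same state, was higher by 0.55 ± 0.13 (adjusted p = 0.00549), which with library totals alone became 0.23 and not called (adjusted p = 0.124). The receptor Trem2, at 0.15 ± 0.12, and the matricellular protein osteopontin, Spp1, at 0.11 ± 0.19, were not called and turned negative with library totals alone, as did the transcription factor Pparg at 0.31 ± 0.12, which was called without DOWN replicate 3 (0.40, adjusted p = 0.0429). The integrin Itgam, at -0.61 ± 0.22 (adjusted p = 0.0620), and the proliferation marker Mki67, at -0.25 ± 0.28, did not pass either, and Mki67 turned to 0.17 without DOWN replicate 4. Itgam was called with library totals alone (-0.93), with no low-count filter and without DOWN replicate 3 or 4 (adjusted p = 0.00431 to 0.0338). Apoptosis and p53 genes rose in 10 and fell in 2, Fas and Mcl1, of 24 cases (10 and 2 adjusted over the list alone, adjusted p = 0.0194 with an estimated correlation), with a median of 0.25 that became -0.07 with library totals alone. Its members Phlda3, Gdf15 and Zmat3 rose by 1.76 ± 0.26, 1.74 ± 0.24 and 1.38 ± 0.17. NF-kB inflammatory genes fell in 8 and rose in 2, Il1a and Tnfaip2, of 31 cases (10 and 3 adjusted over the list alone, median -0.63; adjusted p = 0.472 with an estimated correlation). The adaptor Traf1 stood at -4.20 ± 0.57 and the receptor Cd40 at -2.43 ± 0.43. That list no longer passed camera without DOWN replicate 3 (adjusted p = 0.0906). Cytosolic ribosomal protein genes fell in 8 of 61 cases (8 adjusted over the list alone, median -0.15; adjusted p = 0.856 with an estimated correlation), and the camera call ended in 6 of the 12 fits without a library (UPBIG replicates 1 and 2, UPSMALL replicates 1 and 3, DOWN replicates 1 and 4; adjusted p = 0.0506 to 0.294), with size factors and under a stricter low-count filter (0.0564 to 0.0567).

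In this comparison the median, mean and test of the fatty acid synthesis, cell fusion, alveolar type 2, airway and alveolar type 1, neutrophil and B cell lists differed in sign, and none of those lists was called by camera, though fry called alveolar type 2 as lower (adjusted p = 0.0363). The same held for fatty acid synthesis, cell fusion, alveolar type 2 and neutrophil lists between UPBIG and UPSMALL, and for fatty acid synthesis, cell fusion, growth factor, interferon and neutrophil lists between UPSMALL and DOWN. Of these, fry called fatty acid synthesis between UPSMALL and DOWN as higher (adjusted p = 0.0295), and camera called it without DOWN replicate 3 (0.0468) and the interferon list without UPSMALL replicate 1 (0.0131).

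The largest rise in counts assigned to a named gene lay outside these programmes. Lrrc14b, a leucine-rich repeat gene at chromosome 13, 74359578 to 74364005 in mm10, stood at 44.8 ± 8.60 CPM (SD, n = 4) in UPBIG, from 2888 counts. It had 0 counts in the DOWN libraries, at least 1265-fold lower by a floor of 3 counts over the group, and 5 in the UPSMALL libraries, a ratio of 793 (95% counting interval 339 to 2443). Its fitted log2 fold change against UPSMALL was 9.47, and 10.25 without UPSMALL replicate 3. The gene lies within Ccdc127 on the other strand, which was not called (0.58 ± 0.22, adjusted p = 0.0767). Whether the counts come from Lrrc14b transcript or from an unannotated transcript at this locus was not examined, since reads were not used here. The nearby Sdha, a subunit of succinate dehydrogenase, was higher by 0.59 ± 0.10, a call that ended with library totals alone (0.27, adjusted p = 0.0703). Also called nearby were the ferritin pseudogene Ftl1-ps1, at 0.79 ± 0.14, and Gm47428, at 1.02 ± 0.17. Cxcr1, a chemokine receptor best known from neutrophils, rose by 4.15 ± 0.43, or 4.77 without DOWN replicate 1. The club cell secretoglobin Scgb1a1 rose by 3.45 ± 0.99, with UPBIG replicate 2 at 212 CPM against 13.02 to 18.3 in the other UPBIG libraries. Without that library it was 1.44, and leaving out any of the 8 UPSMALL or DOWN libraries ended its call (adjusted p = 0.0511 to 0.101), as did limma-voom, no low-count filter and a fit of only the 8 libraries compared (0.0717 to 0.169). With library totals alone the median of all tested genes moved from -0.03 to -0.36 and the calls became 518 higher and 3237 lower, so small rises in this comparison are rises relative to the other genes.

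**Figure D2:**
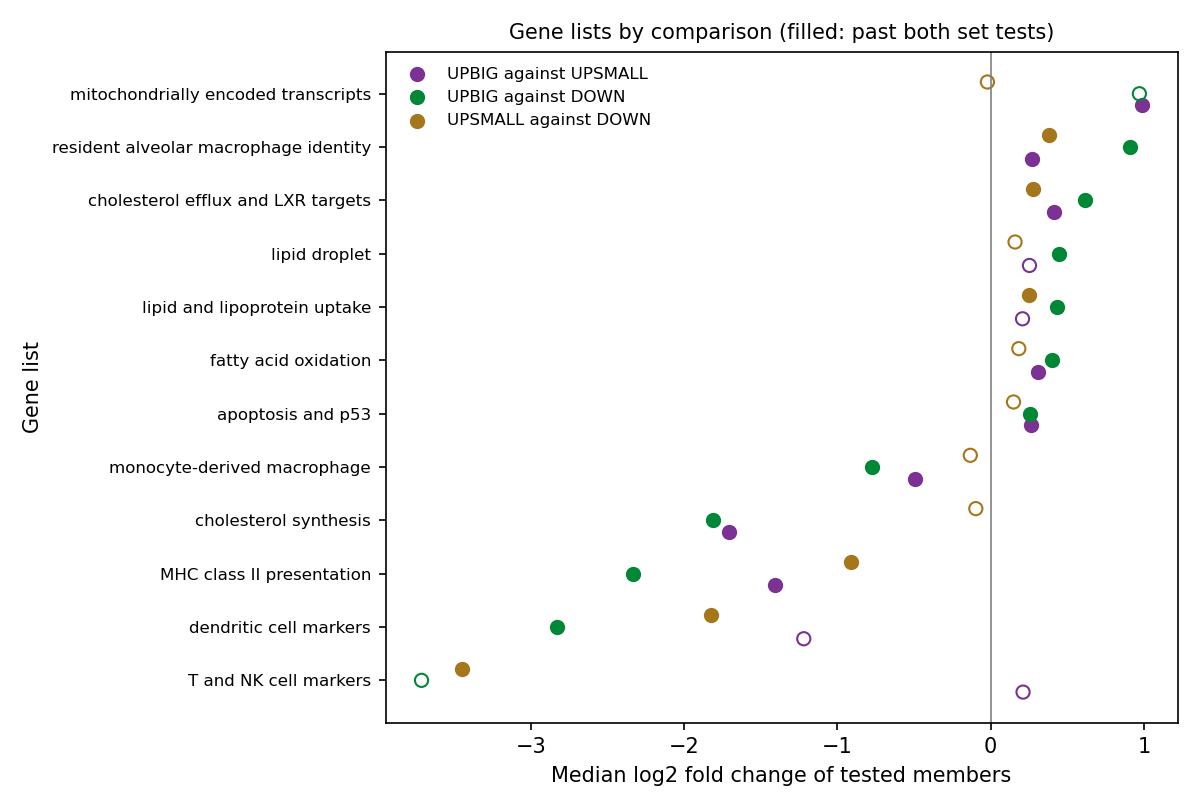
Each point is the median log2 fold change of the tested members of a gene list in a comparison, for 12 lists. Filled points pass camera with the preset and with the estimated correlation; cholesterol synthesis lies at -1.71 and -1.81 in the UPBIG comparisons, and with library totals alone the medians of the resident, lipid droplet, lipid uptake and T and NK lists in UPBIG against UPSMALL and of apoptosis and p53 in both UPBIG comparisons change sign.

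Set against UPSMALL, UPBIG cells again had higher transcripts of liver X receptor targets and fatty acid oxidation and lower transcripts of cholesterol synthesis, MHC class II and monocyte origin. Scd1 and Apoc1 were higher by 3.77 ± 0.16 and 2.84 ± 0.19 on the log2 scale, and Abca1 stood at 334 ± 31.4 CPM in UPBIG against 74.0 ± 5.71 in UPSMALL (SD, n = 4). Sqle, the squalene epoxidase, stood at -3.01 ± 0.25. Cx3cr1 and Ccl17 were lower too, at -3.87 ± 0.31 and -2.96 ± 0.34. In all, 720 genes differed, 406 higher and 314 lower in UPBIG, and 291 of them by more than 2-fold.

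The sterol lists moved as groups here too. Cholesterol synthesis genes fell in 22 of 25 cases (24 adjusted over the list alone, median -1.71; adjusted p = 0.00128 with an estimated correlation). Fdft1 stood at -2.29 ± 0.14 and Stard4 at -2.48 ± 0.22. Liver X receptor targets rose in 7 of 19 cases (13 adjusted over the list alone, median 0.41; adjusted p = 0.00128 with an estimated correlation). That median became 0.13 with library totals alone. Abca1 stood at 2.18 ± 0.17. Fatty acid oxidation genes rose in 9 of 29 cases (12 adjusted over the list alone, median 0.31; adjusted p = 0.0117 with an estimated correlation). The fatty acid oxidation median became 0.04 with library totals alone. Pdk4 stood at 3.43 ± 0.39, Acot1 at 2.57 ± 0.31 and Acadl at 1.26 ± 0.11. Mitochondrially encoded transcripts rose in 10 of 13 cases (10 adjusted over the list alone, median 0.98; adjusted p = 0.0161 with an estimated correlation). mt-Cytb stood at 1.17 ± 0.19 and mt-Nd4 at 1.03 ± 0.14. Lipid droplet genes rose in 3 of 27 cases, Mgll at 1.72 ± 0.15, Plin2 at 1.11 ± 0.14 and Plin3 at 0.53 ± 0.11, the last not called with library totals alone (0.25, adjusted p = 0.164). That list had 3 higher and 2 lower adjusted over the list alone and adjusted p = 0.0567 with an estimated correlation, and its median of 0.25 became -0.02 with library totals alone. Uptake genes rose in 5 cases, which included Cd36 at 2.13 ± 0.22, Fabp4 at 1.52 ± 0.21 and Fabp5 at 0.90 ± 0.17, and fell in 2 of 20, among them Msr1 (5 and 4 adjusted over the list alone, adjusted p = 0.0952 with an estimated correlation). The uptake median of 0.21 became -0.07 with library totals alone, and its camera call ended there and without UPBIG replicate 3, UPSMALL replicate 3 or UPSMALL replicate 4 (adjusted p = 0.0513 to 0.115), as it did under a stricter low-count filter (0.0614).

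Identity genes again set UPBIG apart. Resident alveolar macrophage genes rose in 8 and fell in 1, Car4, of 25 cases (8 and 1 adjusted over the list alone, adjusted p = 0.0222 with an estimated correlation), with a median of 0.27 that became -0.0041 with library totals alone. Besides Fabp4 and Abcg1 they included Ear2 at 0.84 ± 0.11. Siglecf was higher by 0.57 ± 0.16 (adjusted p = 0.0405), a call that ended with library totals alone (0.30) and in 7 of the 12 fits without a library, those of the UPBIG libraries and of UPSMALL replicates 1, 2 and 4 (adjusted p = 0.0622 to 0.106). Monocyte-derived macrophage genes fell in 8 of 25 cases (10 lower and 1 higher adjusted over the list alone, median -0.50; adjusted p = 0.00629 with an estimated correlation). Tgfbi stood at -1.48 ± 0.13. MHC class II genes fell in 9 of 14 cases (9 adjusted over the list alone, median -1.41; adjusted p = 0.0344 with an estimated correlation). H2-Eb1 stood at -2.22 ± 0.22 and H2-DMb2 at -1.88 ± 0.26. Dendritic cell markers fell in 2 of 15 cases, Flt3 and Dpp4 (2 adjusted over the list alone, median -1.22; adjusted p = 0.104 with an estimated correlation), and neither gene was called by limma-voom (adjusted p = 0.182 and 0.122). The dendritic cell list also lost its camera call without UPBIG replicate 3 or UPBIG replicate 4 (adjusted p = 0.0568 to 0.0721), with library totals alone (0.298) and under a stricter low-count filter (0.392). Dpp4 was not called without UPBIG replicates 2, 3 or 4 or UPSMALL replicates 1 or 3 (adjusted p = 0.0601 to 0.0720). Extracellular matrix genes rose in 2, Sdc3 and Tgm2, and fell in 4 of 26 cases, which were Fn1 at -2.19 ± 0.14, Tgfbi, Mmp14 and Mmp8 (3 and 4 adjusted over the list alone, median -0.44; adjusted p = 0.293 with an estimated correlation), and camera no longer called the list without UPBIG replicate 2 or UPBIG replicate 4 (adjusted p = 0.0524 to 0.101), with library totals alone (0.117) or with no low-count filter (0.0864). The calcium-binding protein gene S100a4 stood at -2.90 ± 0.48, or -2.21 without UPSMALL replicate 4.

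Among the remaining lists, lysosome genes rose in 18 and fell in 3, Arsb, Ctsc and Mitf, of 60 cases (29 and 4 adjusted over the list alone, median 0.31; adjusted p = 0.102 with an estimated correlation). The lysosome median became 0.04 with library totals alone. Scarb2 stood at 0.87 ± 0.10 and Ctsk at 0.76 ± 0.11. NRF2 genes rose in 8 of 34 cases (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.138 with an estimated correlation), with a median of 0.17 that became -0.12 with library totals alone. Gstm1, Txn1 and Fth1 rose by 1.56 ± 0.23, 0.97 ± 0.11 and 0.93 ± 0.15. Scar-associated macrophage genes rose in 6 and fell in 4, Arg1, Fn1, Pdgfb and Mmp14, of 28 cases (12 and 4 adjusted over the list alone, median 0.36; adjusted p = 0.470 with an estimated correlation). Igf1 rose by 1.09 ± 0.14, while Gpnmb at 1.15 ± 0.31 (adjusted p = 0.0569), Cd9 at 0.36 ± 0.13, Cidec at 0.29 ± 0.35, Trem2 at 0.05 ± 0.12 and Spp1 at -0.24 ± 0.19 did not pass. Gpnmb was called by DESeq2, under a stricter low-count filter and without UPSMALL replicate 1 (adjusted p = 0.00990 to 0.0497), and Cd9 by DESeq2 and with no low-count filter (adjusted p = 0.0300 to 0.0407). The scar-associated call ended without UPBIG replicate 1, UPSMALL replicate 3 or UPSMALL replicate 4 (adjusted p = 0.0636 to 0.173), with library totals alone (0.126) and under a stricter low-count filter (0.0634). Trem2 turned to -0.0105 without UPSMALL replicate 4 and Spp1 to 0.0397 without UPSMALL replicate 2. Pparg at 0.27 ± 0.12, Itgam at -0.73 ± 0.22 (adjusted p = 0.0583) and Mki67 at -0.49 ± 0.28 were not called, and Pparg and Trem2 turned negative with library totals alone. Itgam was called by DESeq2, with library totals alone, with no or a stricter low-count filter, with only the 8 libraries compared and without DOWN replicate 2 or 4 (adjusted p = 0.00225 to 0.0449). Apoptosis and p53 genes rose in 5 of 24 cases, Casp8, Ccng1, Gdf15, Mdm2 and Phlda3 (7 adjusted over the list alone, adjusted p = 0.0347 with an estimated correlation), with a median of 0.27 that became -0.0045 with library totals alone. Its highest named member, Phlda3, at 1.06 ± 0.26, was not called without UPBIG replicate 1, UPBIG replicate 4 or UPSMALL replicate 2 (adjusted p = 0.0593 to 0.0634). Casp8 was not called without UPBIG replicates 2, 3 or 4 or UPSMALL replicates 1 or 4 (adjusted p = 0.0518 to 0.0985), nor Ccng1 without UPBIG replicates 3 or 4 or UPSMALL replicates 1 or 2 (adjusted p = 0.0590 to 0.0872), and both calls ended with library totals alone. Cell cycle, oxidative phosphorylation and airway and alveolar type 1 lists passed camera with the preset correlation alone, with 1 lower of 50, 3 higher of 74 and 2 lower of 13 (1, 2 and 3 adjusted over the list alone). Their medians were -0.44, 0.16 and -0.72, and their adjusted p = 0.485, 0.375 and 0.226 with an estimated correlation. The cell cycle gene, Hmgb2, was not called without UPBIG replicates 2 or 4 or UPSMALL replicate 4 (adjusted p = 0.0663 to 0.0692). Of the airway genes Cdh1 and Pdpn, the latter was not called without UPBIG replicates 1, 2 or 4 or UPSMALL replicates 1 or 4 (adjusted p = 0.0830 to 0.124) or with only the 8 libraries compared (0.0641). Of the oxidative phosphorylation genes Sdha, Atp5g1 and Cox5a, Atp5g1 was not called without UPBIG replicates 3 or 4 or UPSMALL replicates 2 or 4 (adjusted p = 0.0507 to 0.0900). Cox5a was called only without UPBIG replicate 2, UPSMALL replicate 4 or DOWN replicate 4 (adjusted p = 0.0554 to 0.142 in the other 9 such fits) and not with no low-count filter (0.0751). Neither was called with library totals alone or with only the 8 libraries compared (adjusted p = 0.0540 to 0.703). The oxidative phosphorylation median became -0.13 with library totals alone, where neither that list nor the airway list was called. Outside the lists, Awat1, a wax ester synthase gene, and Slc40a1, which encodes the iron exporter ferroportin, rose by 2.76 ± 0.33 and 2.52 ± 0.40. The libraries of the 2 groups overlapped for Ccng1, Hmgb2, Pdpn and the apoptosis and p53 score. With library totals alone the median of all tested genes moved from -0.03 to -0.31 and the calls became 189 higher and 1433 lower.

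**Figure D3:**
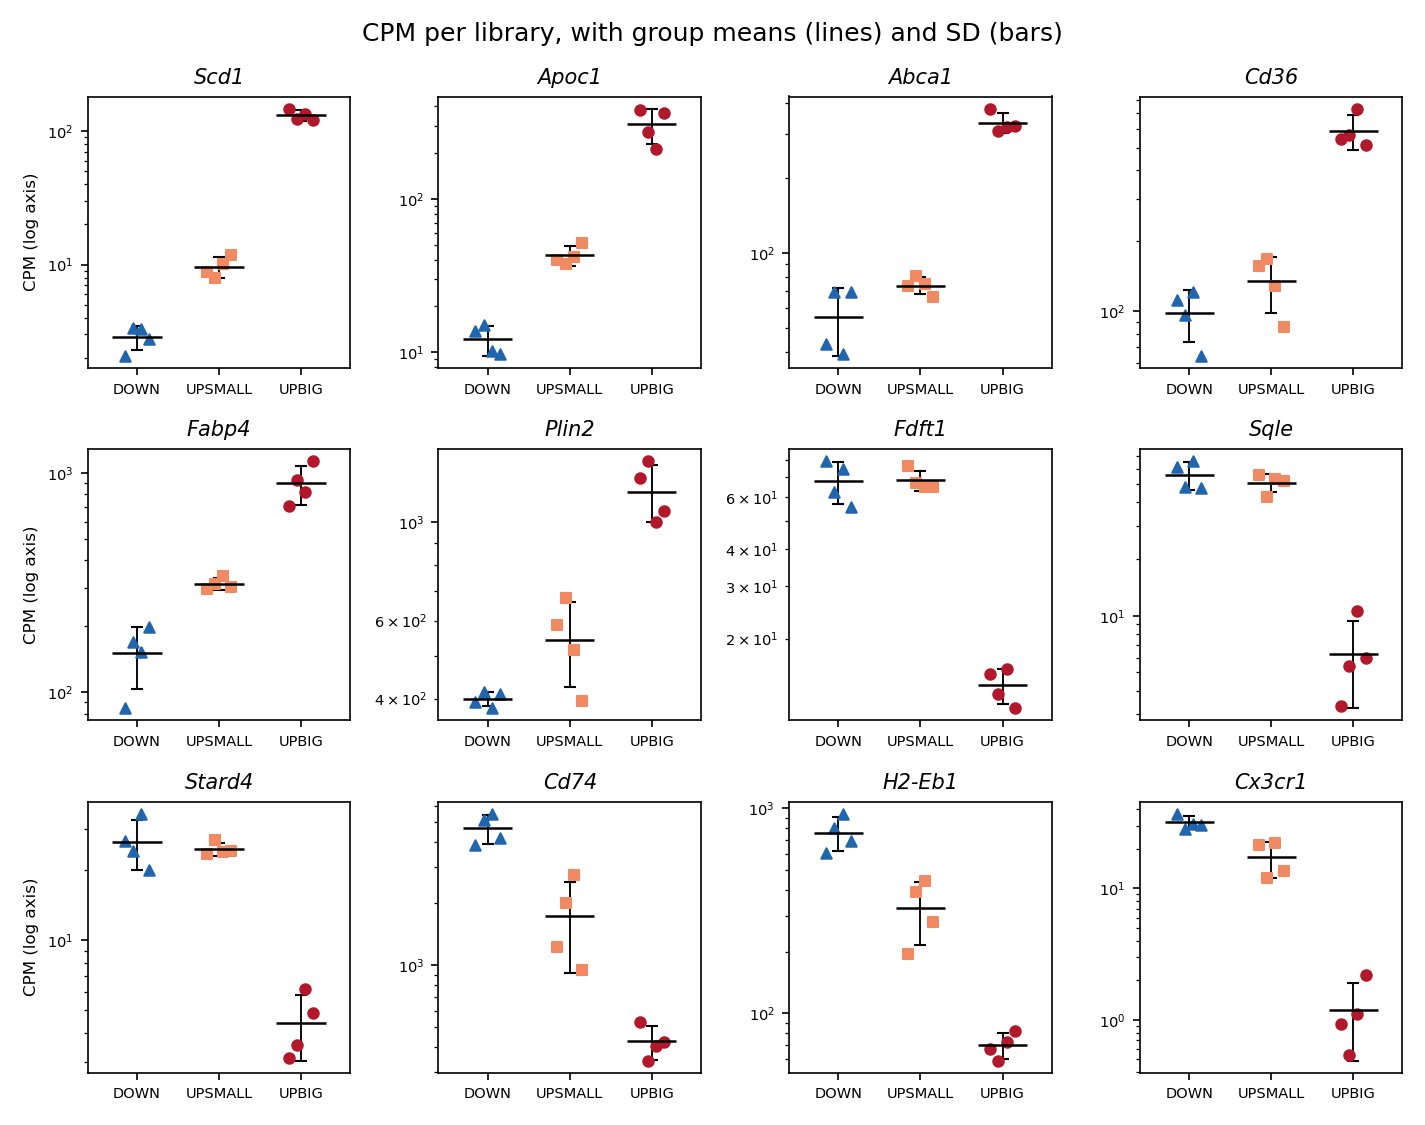
Each point is a library's CPM (log axis) for 12 genes in the 3 groups of 4, with the group mean as a line and the SD as a bar. Scd1 averages 132 CPM in UPBIG, 9.65 in UPSMALL and 2.88 in DOWN, while Fdft1 averages 13.9, 68.2 and 67.9.

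Fewer genes separated UPSMALL from DOWN cells, and they included lipid-linked and resident genes on one side and lymphocyte and antigen presentation genes on the other. Apoc1 and Scd1 were higher in UPSMALL by 1.81 ± 0.19 and 1.75 ± 0.17 on the log2 scale, and Marco, a scavenger receptor of alveolar macrophages, by 2.47 ± 0.33. The T cell receptor and co-receptor transcripts Trac, Cd3d and Trbc2 fell, at -4.20 ± 0.54, -4.14 ± 0.52 and -4.11 ± 0.42. In all, 144 genes differed, 75 higher and 69 lower in UPSMALL, and 93 of them by more than 2-fold. The count ranged from 58 to 179 without single libraries, and fell to 58 without UPSMALL replicate 1, 65 without DOWN replicate 3, 75 without DOWN replicate 1 and 85 without UPSMALL replicate 3 or DOWN replicate 2.

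Cholesterol synthesis, which set UPBIG apart, showed no called gene here among 25 by edgeR, with 1 higher at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (median -0.10). Mitochondrially encoded transcripts had 0 of 13 called by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05 (median -0.02). That either list differs between comparisons was not tested. Liver X receptor targets rose in 2 of 19 cases, Apoc1 and Scd1 (6 adjusted over the list alone, median 0.28; adjusted p = 0.0251 with an estimated correlation). Resident alveolar macrophage genes rose in 5 of 25 cases (11 adjusted over the list alone, median 0.38; adjusted p = 0.00522 with an estimated correlation), which were Marco, Ear1 at 1.17 ± 0.16, Fabp4, Siglecf and Plet1. Of these, Fabp4 at 1.05 ± 0.20 was not called without any single UPSMALL library or DOWN replicate 3 (adjusted p = 0.0565 to 0.0721). Siglecf, at 0.68 ± 0.16, was called only without UPBIG replicate 1, UPSMALL replicate 4 or DOWN replicate 3 and not in the other 9 such fits (adjusted p = 0.0537 to 0.133). Plet1 was not called without UPSMALL replicates 1 or 3 or DOWN replicate 2 (adjusted p = 0.0501 to 0.0598). Lipid uptake genes rose in 2 of 20 cases, Fabp4 and Marco (4 adjusted over the list alone, median 0.25; adjusted p = 0.00792 with an estimated correlation). Lipid droplet genes rose in 2 of 27 cases, Mgll at 1.59 ± 0.15 and Plin3 at 0.63 ± 0.11 (3 adjusted over the list alone, median 0.16; adjusted p = 0.0567 with an estimated correlation), while Plin2 at 0.45 ± 0.14 and Cidec at 0.99 ± 0.36 did not pass. Plin2 was called by limma-voom, with no low-count filter and without UPSMALL replicate 4 (adjusted p = 0.00845 to 0.0491), and Cidec with no low-count filter (adjusted p = 0.00462). Fatty acid oxidation genes rose in 1 of 29 cases, Pdk4 (6 adjusted over the list alone, median 0.18; adjusted p = 0.104 with an estimated correlation). Pdk4 had 119 counts in UPSMALL and 8 in DOWN, a ratio of 14.2 (95% counting interval 7.00 to 33.8), and its fitted log2 fold change of 3.79 was 5.16 without DOWN replicate 1 and not called by limma-voom (4.39, adjusted p = 0.0864).

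T and NK cell markers fell in 7 of 18 cases (14 adjusted over the list alone, median -3.45; adjusted p = 0.00522 with an estimated correlation), and the lymphocyte membrane gene Ms4a4b fell by 3.61 ± 0.48. Dendritic cell markers fell in 1 of 15 cases, Xcr1 (7 lower and 1 higher adjusted over the list alone, median -1.82; adjusted p = 0.00522 with an estimated correlation, and 0.390 by camera under a stricter low-count filter). MHC class II genes fell in 3 of 14 cases, H2-Aa, Cd74 and H2-Eb1 (12 adjusted over the list alone, median -0.91; adjusted p = 0.0155 with an estimated correlation). Xcr1 was not called without UPSMALL replicates 1 or 3 or DOWN replicates 1 or 3 (adjusted p = 0.0604 to 0.0913), and H2-Aa without UPSMALL replicates 2 or 4 or DOWN replicates 2 or 3 (adjusted p = 0.0607 to 0.0810). H2-Eb1 at -1.22 ± 0.22 was not called without UPSMALL replicate 4 (adjusted p = 0.0557). Cd74, the invariant chain, at -1.42 ± 0.29, was not called in 7 of the 12 fits without a library, those of UPBIG replicate 3, UPSMALL replicates 1 and 2 and each DOWN library (adjusted p = 0.0522 to 0.101 over those fits), nor with no low-count filter (adjusted p = 0.0797). Monocyte-derived macrophage genes fell in 3 of 25 cases, among them Ccr2 and Plac8 (6 adjusted over the list alone, median -0.13; adjusted p = 0.0574 with an estimated correlation). Ccr2 at -1.51 ± 0.28 was not called without UPSMALL replicate 2 or DOWN replicates 1, 2 or 3 (adjusted p = 0.0522 to 0.0721). Plac8 was called only without UPBIG replicate 1, UPSMALL replicate 2 or DOWN replicates 2 or 4, and its adjusted p = 0.0537 to 0.129 in the other 8 such fits. It was -4.51 without UPSMALL replicate 2. With only the 8 libraries compared, Cd74, Plac8 and Siglecf were not called (adjusted p = 0.0682 to 0.0869), nor was Plac8 by limma-voom (0.196) or H2-Aa with no low-count filter (0.0537). The transmembrane gene Tmem176a and the calponin gene Cnn2 fell, at -1.32 ± 0.24 and -1.72 ± 0.27. Cell cycle genes had a median of 0.61, with 1 of 50, Prc1, called (12 adjusted over the list alone, adjusted p = 0.102 with an estimated correlation), and Mki67 stood at 0.24 ± 0.28. Prc1 was not called without UPSMALL replicates 1 or 3 or DOWN replicate 3 (adjusted p = 0.0514 to 0.0567). Lysosome, extracellular matrix and NRF2 lists, with 2 of 60, 1 of 26 and 1 of 34 genes higher (6 higher and 1 lower, 2 higher and 1 lower, and 6 higher adjusted over the list alone), passed camera with the preset correlation alone. Their medians were 0.11, 0.42 and 0.22, and their adjusted p = 0.470, 0.133 and 0.132 with an estimated correlation; the lysosome call ended without UPSMALL replicate 2 (adjusted p = 0.0602). Of the lysosome genes, Ctsf was not called without UPSMALL replicate 1 or DOWN replicate 1, nor Ctsk without UPSMALL replicate 2 or DOWN replicates 2 or 3 (adjusted p = 0.0522 to 0.0676). The NRF2 gene, Txn1, was not called without UPBIG replicates 2 or 4, UPSMALL replicates 1 or 3 or DOWN replicates 1, 2 or 3 (adjusted p = 0.0514 to 0.159), nor with library totals alone or only the 8 libraries compared (0.0837 to 0.103). Oxidative phosphorylation genes had 0 of 74 called by edgeR, 6 higher and 2 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom (median 0.11; adjusted p = 0.607 with an estimated correlation), and the list call ended without UPSMALL replicate 4 or DOWN replicate 2 (adjusted p = 0.0528 to 0.0618) and with library totals alone (0.0568). Of the other genes chosen in advance, Gpnmb at 0.67 ± 0.31, Spp1 at 0.35 ± 0.19, Cd9 at 0.19 ± 0.13, Trem2 at 0.10 ± 0.12, Itgam at 0.12 ± 0.22 and Pparg at 0.04 ± 0.12 were not called. Itgam turned to -0.0085 without DOWN replicate 3 and -0.0049 without DOWN replicate 4, and Pparg to -0.0237 without UPSMALL replicate 2. The ribosomal RNA-like CT010467.1 rose by 2.59 ± 0.43, a call that ended without any single DOWN library (adjusted p = 0.0578 to 0.0874).

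The changes were shared across comparisons. Of the genes called between UPSMALL and DOWN, 131 were also called between UPBIG and DOWN, 68 higher and 63 lower in both, where independent lists would share 6.77 and 5.85. Both comparisons use the DOWN libraries, so simulated groups with no effect were fitted 20 times, and they shared at most 0 genes. Without an effect few genes can pass in either comparison, so this count was close to fixed beforehand and is no measure for the 131. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.705 against 0.496 in those simulations, with a covariance of 0.394 against 0.0887. With the DOWN libraries divided between the comparisons, r was 0.309 to 0.329 and 27 to 61 genes were shared. In those fits 33 to 90 genes were called between UPSMALL and DOWN and 1295 to 1483 between UPBIG and DOWN. The simulations kept the shared libraries together, so they give no reference for the divided r. The overlap was 56 to 156 genes without single libraries: 56 without UPSMALL replicate 1, 61 without DOWN replicate 3, 71 without DOWN replicate 1, 80 without DOWN replicate 2 and 82 without UPSMALL replicate 3. Between UPBIG against UPSMALL and UPBIG against DOWN, 672 genes were shared, 382 higher and 290 lower in UPBIG in both. Independent lists would share 36.7 and 26.6, and the simulations, again with few genes to share, shared at most 1. There r was 0.744 against 0.509 in simulations. When the UPBIG libraries were divided, r was 0.313 to 0.375 with 298 to 339 shared genes, again without a simulated reference. In those fits 370 to 480 genes were called between UPBIG and UPSMALL and 1188 to 1669 between UPBIG and DOWN.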

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

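The tests of dendritic cells, library scaling, sequencing depth and other splits of the samples were chosen only after the result was seen, apart from the splits for lists with an estimated correlation; the tests of gene length and GC content, abundant genes and long transcripts were set before theirs.

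MHC class II transcripts were lower in UPBIG than in UPSMALL and DOWN, and markers of dendritic cells, which carry MHC class II themselves, were lower than in DOWN, while against UPSMALL 2 of 15 were called (adjusted p = 0.104 with an estimated correlation). The summed CPM of the 10 called MHC class II genes was 1135 in UPBIG, 4278 in UPSMALL and 10227 in DOWN, and UPSMALL reached 34.6% of the rise (25.6% to 43.4% over sets without 1 library per group), while 9 called dendritic cell markers, with sums of 9.51, 23.3 and 89.3, reached 17.3% (7.29% to 25.9%). The share was higher for MHC class II in 64 of 64 sets, but the sets share libraries, the 2 ranges meet, and the test takes dendritic cells to carry these genes in 1 ratio in each group, which was not measured. Of the 16 listed dendritic cell markers 3 stand in other lists and 6 of 15 tested averaged 1 CPM or more in UPBIG, and the labels name no marker gate that would remove such cells. Both gene sets were taken because they were called lower between UPBIG and DOWN in these same libraries. Of 25 genes of monocyte-derived macrophages, 10 also fell there and 1 rose. So dendritic cells as the whole source, fewer monocyte-derived cells and a difference between the macrophages themselves cannot be told apart. A part played by monocyte-derived cells and a difference between the macrophages are untested.

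Cholesterol synthesis genes were lower and liver X receptor targets higher in UPBIG. With library totals alone the median of the liver X receptor list between UPBIG and DOWN moved from 0.62 to 0.29. Cholesterol synthesis stood at -2.12 there. Camera still called the liver X receptor list (adjusted p under 0.05, and at most 0.00128 over the alternatives run). That test sets a list against all other genes, so this call says little about scaling. The opposite signs of the medians argue against scaling as the whole cause, since scaling moves the genes of a library alike. After the trend on gene length and GC content was removed, the 25 cholesterol synthesis genes kept a median of -1.79. That trend held 1.14% of the variance of the fold changes across genes, so this outcome was close to fixed. The weakness of the trend, rather than the outcome, argues against it. A difference in sterol content between the sorted populations could give this pair of changes and stays open, since no sterol was measured.

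UPBIG libraries held fewer detected genes than DOWN. Thinned to 1 total in a single random draw, they still held fewer by a mean difference of -816 (exact permutation test, adjusted p = 0.06). The groups came close there, with UPBIG replicate 2 at 16096 and DOWN replicate 3 at 16114. This argues against depth as the whole cause, but weakly. Loss of long transcripts stays open: the Spearman rho across 12613 genes between transcript length and fold change was -0.0704, above the -0.1 set beforehand, but that bound was too strict, since rho stayed below 0 without each library (-0.08 to -0.05), the sign that such a loss gives. Outside Lyz2, Ftl1 and Fth1, at 12123358 counts per library, the difference was -653. The groups overlapped there, with UPBIG replicate 2 at 16037 and DOWN replicate 3 at 15946. That step also lowered the thinned total from 17109642. It therefore cannot tell whether a few abundant genes taking more counts account for part of the difference. A narrower repertoire in these cells stays open and untested.

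Of the 35 ways to split each pair of groups, 1 (the real one) gave as many called genes. The highest of the other splits called 0 by edgeR, against 720, 2210 and 144 genes. The other splits mix the real groups, so real differences add to their spread and a low count there was close to fixed. As 1 of 35 is also the smallest share these splits can give, they argue against chance but do not exclude it. For any difference among the groups, 1 of 100 splits gave as many as the real 1736, and the highest other, 924, kept UPBIG whole and exchanged UPSMALL replicate 1 with DOWN replicate 1. For lists called with the preset correlation the splits cannot decide on chance. For UPBIG against UPSMALL 3 of 35 splits, for UPBIG against DOWN 3 and for UPSMALL against DOWN 11 gave as many as the real 18, 18 and 14, and the highest others gave 18, 19 and 18. Nearly all of the other splits that reached these counts exchanged 1 library between the groups, and so kept much of the real difference. With the estimated correlation 1 of 35 splits in each comparison gave as many as the real 8, 10 and 6. The highest others gave 1, 0 and 1, which argues against chance within the same limits.

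In 14 of 414 groups of 4 libraries (3.38%) a library stood far from the others, where chance gives about 1 in 20. The value given is the gap to the nearest library over the group's range, on the log2 scale for genes. Scgb1a1 in UPBIG gave 0.879, with replicate 2 at 212 CPM against 13.02 to 18.3. The airway and alveolar type 1 score in UPBIG gave 0.913, again with replicate 2, at 3.02 against 1.07 to 1.24. In UPSMALL, replicate 4 stood apart for Gstm1 (0.907; 412 CPM against 763 to 812), Fth1 (0.848; 40560 against 57112 to 60720) and Tgfbi (0.833; 667 against 453 to 484). The mitochondrial gene mt-Nd4 in UPBIG gave 0.848, with replicate 1 at 2658 CPM against 3193 to 3300. Cd83 in DOWN gave 0.947, with replicate 3 at 38.6 CPM against 33.6 to 33.8. Traf1 in UPBIG gave 0.907, with replicate 4 at 0 against 0.527 to 0.658. Dpp4 and Flt3 in UPBIG each gave 1, from a single count in replicate 1 (0.0623 CPM) and in replicate 3 (0.0586 CPM). In DOWN, replicate 1 stood low for Flt3 (0.841; 1.73 CPM against 4.57 to 5.48) and Prc1 (0.845; 1.30 against 4.01 to 4.90). UPSMALL replicate 1 stood high for the lipid droplet score (0.877; 4.64 against 4.31 to 4.35) and for the share of the ribosomal RNA-like CT010467.1 (0.930; 1.10% against 0.368% to 0.420%).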

How the results depend on the processing

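The settings without ribosomal RNA-like and mitochondrial transcripts and without the 3 most abundant genes were chosen only after the result was seen; the others were planned. No called gene or list named in the text reversed under any setting run, except that list medians changed sign with library totals alone. Of 149 gene calls, 148 of 148 fitted were kept by DESeq2, 149 with size factors, 145 without a low-count filter, 142 by limma-voom, 139 with library totals alone, 121 in every fit without a library and 94 against a minimum fold of 1.5. Of 50 list calls, 24 were kept with an estimated correlation, 45 by fry, 44 with the stricter filter, and 42 with library totals alone or in every fit without a library. The settings added later gave 707 and 719, 2177 and 2205, and 144 and 146 genes for UPBIG against UPSMALL, UPBIG against DOWN and UPSMALL against DOWN. Library totals alone gave 1622 genes for UPBIG against UPSMALL (502 shared), 3755 for UPBIG against DOWN (1588 shared), 3021 for any difference and an overlap of 1420 between the UPBIG comparisons, since they shift the median of all genes downward in UPBIG. DESeq2 gave 1087 for UPBIG against UPSMALL and, for UPSMALL against DOWN, 433 with an overlap of 360. For the latter comparison limma-voom gave 226 (overlap 205) and no low-count filter 460 (overlap 361). A minimum fold of 1.5, a stricter null by construction, gave 143, 597 and 25. The estimated correlation left 8, 10 and 6 lists. Replicate numbers did not meet a rule that every same-number pair correlates over 0.1, which is strict and cannot exclude pairing. Residuals of these pairs correlated at -0.03 to 0.15, over 0.1 in 6 of 12, against 2 of 36 pairs of different numbers. The 3 pairs of number 2 all passed 0.1 and 8 of 12 libraries correlated best with their own number. Pairing therefore stays open, and the chosen fit, which has no block, would ignore it. With the number as a replicate block, 1025, 2607 and 275 genes, 2220 for any difference, overlaps of 247 and 918, and 17, 18 and 15 lists were called. With it Gpnmb (adjusted p = 2.35e-06), Itgam (0.0132) and Cd9 (0.0228) were called between UPBIG and UPSMALL, Itgam (0.0264) and Pparg (0.0495) between UPBIG and DOWN, and Gpnmb (0.00639) and the scar-associated list (0.0187) between UPSMALL and DOWN. Not called with it were the dendritic cell list between UPBIG and UPSMALL (0.0632), Scgb1a1 between UPBIG and DOWN (2.47, 0.142), and Cd74 (0.0594) and Plac8 (0.0529) between UPSMALL and DOWN. It changed no other call of a list or a gene that the rule names. The scar-associated list was also called there with no low-count filter and without UPSMALL replicate 3, UPSMALL replicate 4 or DOWN replicate 2 (0.00682 to 0.0373). Among other lists not called between UPSMALL and DOWN, of 21 alternatives 11 called the NF-kB list (adjusted p = 0.0522 by the chosen fit, 0.00170 to 0.0301 where called), 11 airway and alveolar type 1 (0.0517, 0.00170 to 0.0367 where called), 5 apoptosis and p53, 3 ribosomal protein, 2 fatty acid synthesis and 1 interferon. Between UPBIG and UPSMALL 6 called NF-kB, 4 stress response, 4 ribosomal protein, 2 interferon, 1 glycolysis and 1 T and NK cells. Between UPBIG and DOWN 4 called cell cycle, 2 glycolysis, 1 stress response and 1 alveolar type 2. Without single libraries, genes ranged from 500 to 762, 1777 to 2421, 58 to 179 and, for any difference, 1388 to 1938. Lists then ranged from 16 to 21, 17 to 18 and 15 to 18, and the overlaps from 56 to 156 and 474 to 671. The fits at 58, 65, 75, 85 and 85 genes for UPSMALL against DOWN lack UPSMALL replicate 1, DOWN replicate 3, DOWN replicate 1, DOWN replicate 2 and UPSMALL replicate 3, and their overlaps were 56, 61, 71, 80 and 82; fewer samples lower the power. Among genes not called, library totals alone turned Pparg to -0.0032, Trem2 to -0.17 and Spp1 to -0.21 between UPBIG and DOWN, and Pparg to -0.0041 and Trem2 to -0.22 between UPBIG and UPSMALL. Without single libraries, Mki67 ranged from -0.44 to 0.17 between UPBIG and DOWN, positive without DOWN replicate 4. Between UPBIG and UPSMALL, Trem2 ranged from -0.0105 to 0.12, negative without UPSMALL replicate 4, and Spp1 from -0.37 to 0.0397, positive without UPSMALL replicate 2. Between UPSMALL and DOWN, Itgam ranged from -0.0085 to 0.34, with -0.0049 without DOWN replicate 4 and the lowest without DOWN replicate 3, and Pparg from -0.0237 to 0.13, negative without UPSMALL replicate 2. Where no construction is named, the cause was not tested. In simulated data DESeq2 called 18 to 28 unchanged genes per comparison against 5 or 6 by edgeR. It also recovered more of the 2-fold changes, 56% to 66% against 52.5% to 60.6%. Those counts were drawn from the spread that edgeR had fitted, which may favour edgeR, so they do not rank the tools on the real data. Depth limits genes with few counts, such as Flt3 and Dpp4 in UPBIG.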

Other observations

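All genes in this part and the iron handling test were chosen only after the result was seen.

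Genes that neutrophils are known for did not move as a group in UPBIG. S100a8, a calcium-binding alarmin subunit, stood at 375 ± 15.2 CPM in UPBIG (SD, n = 4), 169 ± 25.9 in UPSMALL and 128 ± 16.5 in DOWN, a log2 fold change of 1.55 ± 0.12 (SE) against DOWN. Its usual partner S100a9 averaged 2.55, 1.36 and 7.26 CPM and was not called. Cxcr2, the neighbour of Cxcr1 on chromosome 1, stood at 16.4 ± 1.71, 2.88 ± 1.13 and 1.35 ± 0.686 CPM. The carbonic anhydrase Car4, counted among resident alveolar macrophage genes, went against its list, at 17.9 ± 11.5 CPM in UPBIG, 127 ± 45.8 in UPSMALL and 88.1 ± 21.3 in DOWN.

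Iron handling genes were examined as a hypothesis, that they move together in UPBIG. Of 22 tested, 9 rose and 3 fell between UPBIG and DOWN (median 0.19). Camera with an estimated correlation gave an unadjusted p = 0.0104, as the hypothesis asks but on the data that prompted it. Between UPBIG and UPSMALL 6 rose and 1, Hfe, fell (median 0.15). Camera with an estimated correlation gave unadjusted p = 0.00233 there and p = 0.538 between UPSMALL and DOWN, where the list did not pass. With library totals alone the median of all tested genes moved from -0.03 to -0.36 against DOWN and to -0.31 against UPSMALL. Both moves are larger than the list medians, and the list was not tested under that setting. The transferrin receptor Tfrc rose by 2.67 ± 0.29 and the exporter Slc40a1 by 2.81 ± 0.40 against DOWN, and the ferritin chains Fth1 and Ftl1 by 1.16 ± 0.15 and 0.87 ± 0.15. The ferritin receptor Ncoa4 rose by 0.82 ± 0.10, while Hfe, Ireb2 and Slc25a37 fell, at -0.74, -0.72 and -0.74.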
